A study of Mus musculus with 2 samples.

How the data were processed

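RNA was profiled from primary mouse embryonic fibroblasts taken at embryonic day 13.5 from matings of heterozygous parents. One library was labelled wild type and the other knockout for Sptbn1, given as homozygous in the series' title, the gene of beta-2 spectrin (also called β2SP), a scaffold protein of the membrane skeleton. Per the labels' protocols, total RNA was extracted with a phenol-based reagent, and 1 µg of it went into each library, made with the Illumina TruSeq RNA kit. Each genotype had 1 library, so no difference has a replicate check, no SD or p-value of its own is given, and every statement compares 2 libraries, not 2 conditions.

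The series' design text names an Illumina HiSeq 2000, FastQC and Trimmomatic for read quality and adaptors, TopHat2 version 2.0.10 for alignment to NCBI mouse build 37.2, Cufflinks with the matching gene models for quantification and normalisation, and Cuffdiff2 for the comparison. Other versions and settings are not given in the sources used here. Per the file headers, the authors deposited 1 table of FPKM (fragments per kilobase of transcript scaled to the number of mapped fragments) per gene for each library, a log2 fold column and a p-value column. One FPKM column is headed by the Sptbn1 knockout name. The other carries both a wild-type mark and a -/- mark in its header and was taken as wild type because its name matches that library's title. Every direction given here rests on this reading of the headers, and Sptbn1 was the lower in the column taken as knockout. FPKM from Cufflinks are estimates in which fragments shared between near-identical genes are divided, so levels of ribosomal protein genes, histone genes, small RNA genes and genes with processed copies are uncertain. Gapdh, which has many processed copies, was listed at 0.566 FPKM in the knockout library and 0.351 FPKM in the wild-type library (chosen after its values were seen). A value of 0 may also be a failed estimate, and such genes are only said to be listed at 0.

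The table held 25587 rows and 25430 distinct names, of which 177 joined several genes of 1 locus. For a repeated name the row with the highest mean FPKM was used. Symbols were matched to the NCBI RefSeq gene table of the GRCm38.p6 assembly, which lists older names. Joined names were split and each part was counted: 19937 matched a symbol, 2891 matched an older name and 2850 matched neither and were kept as deposited. That table served for names and gene order, and GENCODE vM21 transcripts for lengths. Both are on another build than the one the reads were aligned to, so no coordinates are given. Current symbols are printed, and Sptbn1 is listed in the table as Spnb2.

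The deposited FPKM columns summed to 279927 in the knockout library and 386567 in the wild-type library. Total fragment counts are not given in the sources used here. Among 3100 rows above 0 in both libraries with a mean below 0.3 FPKM, the commonest log2 ratio of knockout over wild type was 0.69, shared by 396 rows within 0.005, and 310 further rows lay 1 log2 step below it. One fragment was thus worth 1.61 times as much FPKM in the knockout library, which gives relative depth (the knockout library the shallower) but no absolute depth. No interval or detection floor was therefore computed.

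Differences are log2((knockout FPKM + 1)/(wild-type FPKM + 1)), which understates the change of low genes. A gene was called measured when its mean FPKM over both libraries was 1 or more, which held for 11070 genes, and differences of 2-fold or more on this scale were counted. Before the data were examined, 36 gene lists were fixed for the membrane skeleton, TGF-β and other signalling, imprinting, cell cycle and repair, matrix, inflammation, metabolism, other cell types, sex and library composition. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from measured genes within 20 bins of mean FPKM. A median outside the central 95% of these is said to stand apart, as a description of these libraries. The percentiles take genes as exchangeable, which coregulated genes are not.

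The named genes followed a rule fixed beforehand. It took Sptbn1, the 12 highest and 12 lowest log2 ratios among 5277 genes with a mean of 5 FPKM or more (names with the prefixes of predicted, micro, small nucleolar, small Cajal body and small nuclear RNA genes left out, which does not catch Rn7sk, Rpph1 and MBI-39), 6 genes chosen for the question (Igf2, H19, Cdkn1c, Ctcf, Tert and Smad3), and up to 4 measured members of each list with the largest differences. Other genes were named after their values were seen, among them members that belong to more than 1 list (Ctss, Acta2 and Tagln). The names left out by prefix stayed in the counts. Values of a few genes that the rule takes are not reported here.

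Alternatives fixed beforehand were a pseudocount of 0.1 FPKM, scaling to a median log2 ratio of 0, to a common upper quartile or to a common FPKM sum, no filter or a mean of 5 FPKM, FPKM summed over the rows of a symbol, small RNA genes left out by name prefix and a size limit of 4-fold. One was added after the data were seen, a common FPKM sum without small RNA genes, ribosomal RNA and 3 outlying rows. The added scaling left out LOC236598, Filip1l and Dnaja1 as those rows. Random lists numbered 2000 for each alternative.

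The deposited log2 column was not used for any difference. Of 16471 rows above 0 in both libraries, 29 held a log2 value in the authors' deposited table that differed by more than 0.001 from the log2 ratio of the FPKM in the same row, and 1768 cells of the column held a spreadsheet error in place of a number, all in rows with 1 library at 0. To compare the deposited p-values with the fold, the absolute log2 FPKM ratio (without pseudocount) was divided by the normal quantile of the two-sided p-value, which gives the standard error the pair implies. This was set against the running median over the 101 genes nearest in mean FPKM.

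The list percentile was tested on simulated log2 ratios, drawn independently from a normal distribution for the 11070 measured genes. Only the mean FPKM came from these data, and the lists were random genes. Coregulated and outlying genes were thus absent, so the test does not show how the percentile behaves on real lists. With a shift of 0.15 planted in 10 lists it found 6, with a shift of 0.3 it found all 10, and 1 of 20 lists with no shift stood apart. The comparison of p-values with folds was tested on 200 altered rows among 11046 simulated ones, of which it found 146, with 0 others. The simulated standard errors scattered little, so the 0 need not hold for the deposited values. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.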

Results

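Gene expression was measured by RNA sequencing in mouse embryonic fibroblasts, primary connective tissue cells grown from midgestation embryos. There was 1 wild-type library and 1 Sptbn1 knockout library. Values are FPKM as the authors deposited them, and their total fragment counts are not given in the sources used here. FPKM of 1 or more was listed for 10997 gene names in the knockout library and 11098 in the wild-type library. The comparison asks how expression differs between fibroblasts labelled wild type and knockout for the gene of beta-2 spectrin, which the literature describes as an adaptor of Smad3 and Smad4 in TGF-β signalling. With 1 library per genotype no difference could be set against a spread between cultures.

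Sptbn1 was listed at 36.6 FPKM in the knockout library and 69.6 FPKM in the wild-type library, a log2 ratio of -0.91, which left 52.5% of the wild-type value. The direction matched the labels, and the ratio stood at the 1.20th percentile among the 500 genes nearest in expression. FPKM summarise the whole gene, so the table does not show which exons the remaining fragments came from, and the value alone does not establish loss of an intact transcript or of the protein. On a common FPKM sum the log2 ratio was -0.45. In the authors' deposited table the p-value of Sptbn1 was 1.7971e-05. The other spectrin, ankyrin, adducin and protein 4.1 genes, which build the membrane skeleton with Sptbn1, lay nearer to 0. Of 13 measured list members including Sptbn1, 8 were below and 5 above 0, with a median of -0.05 (58.3rd percentile of random lists). Epb41l1 was at -0.38, Epb41l3 at -0.27 and Tmod2 at 0.25.

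Most genes had near-equal FPKM in the 2 libraries. The median log2 ratio of the 11070 measured genes was -0.05, and 97.7% of them lay within 1.5-fold. Across these genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.947 and Spearman's rho 0.973. At least 2-fold higher in the knockout library were 40 genes, and at least 2-fold lower were 42. Names with the prefixes of predicted and small RNA genes made up 24 of the former and 23 of the latter, and the 16 and 19 others still held noncoding RNAs such as Rn7sk and Rpph1. The zero point depends on the scaling, since the FPKM sums differed by a log2 shift of 0.47. On a common FPKM sum, which a single small RNA row (Mir682, chosen after its values were seen, 25.2% of the knockout sum and 29.1% of the wild-type sum) and Dnaja1 (5.59% of the wild-type sum) weighed on, the counts were 104 higher and 26 lower. A pseudocount of 0.1 FPKM gave 60 and 72, and a mean of 5 FPKM or more left 25 and 30. Directions below are on the deposited scale, relative to a median gene at -0.05.

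**Figure D1:**
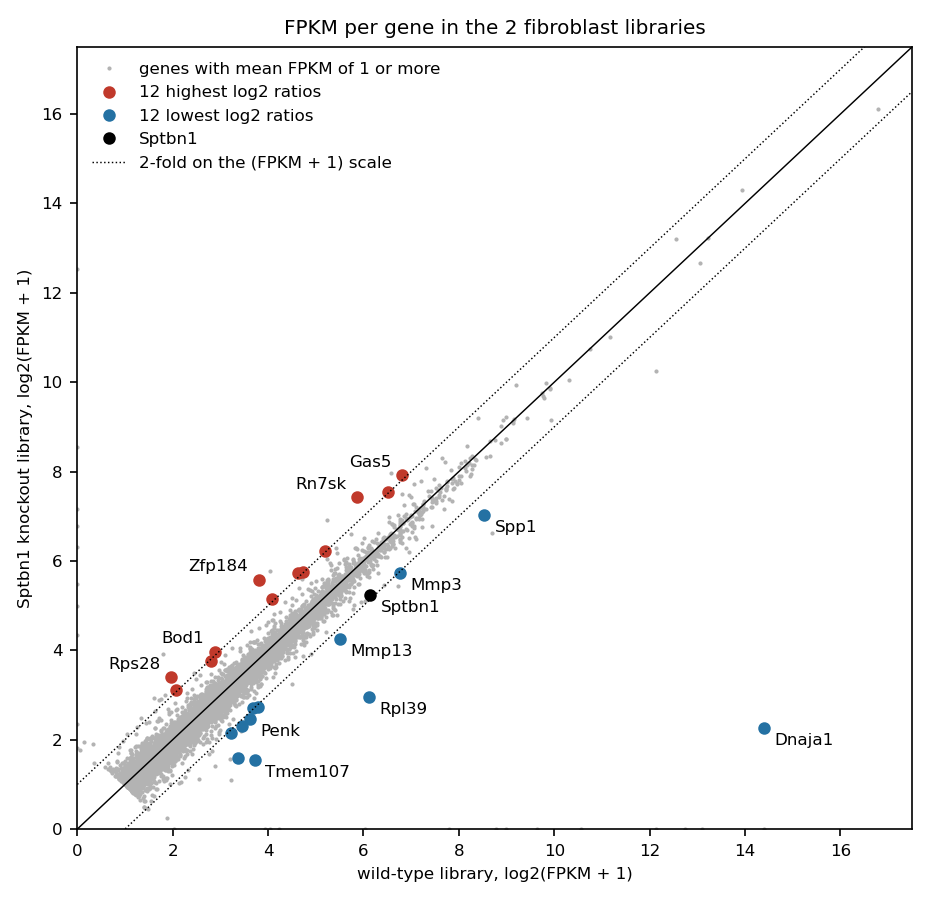
FPKM of each measured gene in the wild-type library (horizontal axis) and the knockout library (vertical axis), both as log2(FPKM + 1), with the 12 highest and 12 lowest named genes and Sptbn1 marked and points on an axis standing for genes listed at 0 in 1 library. Most of the 11070 genes sit along the diagonal, Sptbn1 lies just inside the lower 2-fold line at -0.91, and Dnaja1 is far below it.

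The lowest named genes included secreted matrix and inflammatory products. Spp1, which encodes the secreted phosphoprotein osteopontin, was at 129 FPKM in the knockout library and 368 FPKM in the wild-type library, a log2 ratio of -1.51. The collagenase gene Mmp13 was at 18.1 against 44.2 FPKM (-1.24), and the stromelysin gene Mmp3 at 51.7 against 107 FPKM (-1.04). Ptgds, a prostaglandin D synthase, was at 3.91 against 10.0 FPKM (-1.16), Penk, the proenkephalin precursor, at 4.49 against 11.3 FPKM (-1.16), and the glutathione transferase gene Gsta4 at 3.46 against 8.29 FPKM (-1.06). Bcl2a1b, an antiapoptotic BCL2 relative with near-identical copies, had a log2 ratio of -1.04, and the neutrophil-attracting chemokine gene Cxcl5 one of -0.97. The remaining 4 of the 12 were Dnaja1, Rpl39, Tmem107 and Ube2t. Dnaja1, a heat shock co-chaperone, was listed at 3.79 FPKM in the knockout library and 21626 FPKM in the wild-type library, a log2 ratio of -12.14. It was treated as an outlying row in the scaling added after the data were seen, and its value is given only as deposited. Rpl39 was at 6.71 against 67.9 FPKM (-3.16), Tmem107 at 1.91 against 12.2 FPKM (-2.18) and Ube2t at 1.99 against 9.28 FPKM (-1.78).

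Among the 12 highest named genes were several short or noncoding RNAs. Rn7sk, the 7SK RNA that restrains transcription elongation, was at 171 FPKM in the knockout library and 57.3 FPKM in the wild-type library (1.56), and Rpph1, the RNA of ribonuclease P, was at 52.6 against 25.8 FPKM (1.00). Gas5, a noncoding host gene of small nucleolar RNAs, was at 242 against 111 FPKM (1.11), the ribosomal protein gene Rps28 at 9.60 against 2.90 FPKM (1.44) and the histone gene H4c3 at 7.68 against 3.21 FPKM (1.04). The zinc finger gene Zfp184 had the highest log2 ratio of the named genes above 5 FPKM, 1.77, at 46.9 FPKM in the knockout library, 361% of the wild-type value. The calcium-binding protein gene S100a11 was at 186 against 90.2 FPKM (1.03), and Ucp2, a mitochondrial carrier, at 12.6 against 5.94 FPKM (0.97). Bod1 (1.09) and Anapc13 (1.05), both with roles in mitosis, and MBI-39 (1.11) were also among the 12. Bod1 lies 9 places from Sptbn1 among the protein-coding genes of chromosome 11.

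Of the 36 lists, 28 had at least 5 measured members and 9 stood apart from random lists. By chance 1.4 would, if genes within a list varied independently, which coregulated genes do not. Medians were lower in 4 and higher in 5. All 20 negative list medians, these 4 among them, turned positive on a common FPKM sum, while the 4 kept their place below the central 95% of random lists there. Mir682 and Dnaja1 weighed on that sum. Without small RNA genes, ribosomal RNA and 3 outlying rows, a setting added after the data were seen, the shift was 0.05. The 4 medians stayed negative there. Centring on the median gene turned 10 of the 20, all inside the central 95%, so the signs of medians near 0 carry no direction.

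Matrix protease and inhibitor genes were lower as a group, with 21 of 26 measured members below 0 and a median of -0.25, below all 10000 random lists. On a common FPKM sum this median was 0.17. The collagenase and stromelysin genes Mmp13, Mmp3 and Mmp10 were at least 2-fold lower, with Mmp10 at 1.49 FPKM in the knockout library and 4.01 FPKM in the wild-type library. The macrophage elastase gene Mmp12 was at -0.58. Markers of macrophages and leukocytes, a cell type that fibroblast cultures from embryos can hold, were also lower. Their median was -0.32, with 14 of 16 below 0, again below all 10000 random lists, and 0.11 on a common FPKM sum. The complement genes C1qb (13.7 against 25.4 FPKM, -0.85) and C1qc (-0.56), the joined lysozyme entry Lyz1,Lyz2 (572 against 979 FPKM, -0.77) and the Fc receptor chain gene Fcer1g (52.4 against 77.6 FPKM, -0.56) had the largest differences. None of the 16 reached 2-fold. The lysosomal protease gene Ctss belonged to both lists.

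Interferon-stimulated genes had a median of -0.23, below all 10000 random lists (0.20 on a common FPKM sum), with 21 of 26 below 0. The chemokine gene Cxcl10 was at least 2-fold lower, at 1.04 against 3.38 FPKM (-1.10). The interferon regulators Usp18 and Irf7 were at -0.45 and -0.39, and Oasl2 at -0.38. Cytokine, chemokine and NF-κB target genes went both ways, with 15 of 24 below 0 and a median of -0.14 (0.83rd percentile), which was 0.17 on a common FPKM sum. Among those with a mean of 5 FPKM or more this list no longer stood apart. Cxcl5 was at -0.97 and the interleukin-33 receptor gene Il1rl1 at -0.96 (43.0 against 84.8 FPKM), whereas Lcn2 was at 0.79 and complement C3 at 0.56. The macrophage marker median of -0.32 stands beside both lists.

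The TGF-β family list of ligands, receptors, antagonists and SMADs had 28 of 37 members below 0 and a median of -0.11, at the 2.71st percentile, just inside the central 95% (0.32 on a common FPKM sum). The BMP antagonist gene Grem1 was at 29.4 FPKM in the knockout library and 53.8 FPKM in the wild-type library, a log2 ratio of -0.85. Eng was at -0.30 and Inhba at -0.28, while Smad3 was listed at 4.44 against 4.35 FPKM (0.02). TGF-β-induced target genes of fibroblasts did not stand apart. Their median was -0.03 (78.5th percentile), with 17 of 28 below 0 and none at 2-fold. Cnn1, an actin-binding protein of contractile cells, was at 0.46, Plod2 at 0.32, Tgfbi at -0.29 and Thbs1 at -0.26. BMP target genes had a median of -0.01 (64.6th percentile), with Hey1 at 0.44 and Id4 at -0.35.

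Imprinted genes were slightly higher as a group, with 19 of 28 above 0 and a median of 0.05 (99.8th percentile). None reached 2-fold. Plagl1, a zinc finger gene expressed from the paternal copy, was at 11.9 FPKM in the knockout library and 7.44 FPKM in the wild-type library (0.61), and the noncoding RNA H19 at 297 against 209 FPKM (0.51). Its neighbour Igf2, a fetal growth factor gene, was at 207 against 190 FPKM (0.12), and the cell cycle inhibitor gene Cdkn1c at 10.3 against 11.9 FPKM (-0.19). Zim1 (-0.37) and Inpp5f (-0.36) lay on the other side. Ctcf, which encodes the insulator protein that binds the H19 and Igf2 control region, was at 10.8 FPKM in the knockout library, 98.1% of the wild-type value (-0.03). The list of CTCF, cohesin and DNA methylation genes had a median of -0.02 (79.4th percentile), with Rad21 and Smc1a both at 0.15. The IGF axis had a median of -0.08 (33.2nd percentile), with the binding protein genes Igfbp5 at -0.43, Igfbp2 at -0.41 and Igfbp4 at 0.29.

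Cell cycle and DNA replication genes had a median of 0.03 (99.7th percentile), with 20 of 33 above 0 and none at 2-fold. They no longer stood apart on a common FPKM sum, at the 96.85th percentile. The mitotic genes Kif20a and Cdc20 were each at 0.29 and Ccnb2 at 0.23, while Aurkb was at -0.23. Smooth muscle markers had a median of 0.18 (99.9th percentile), with 7 of 8 above 0. The smooth muscle actin gene Actg2 was at 44.4 against 29.0 FPKM (0.60) and Cnn1 at 17.1 against 12.1 FPKM (0.46), whereas Des was at -0.34. Of these 8 markers, 3 (Acta2, Cnn1 and Tagln) were also on the list of TGF-β targets.

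Histone genes and ribosomal protein genes, which report on library composition, also stood apart. Histone genes, most of whose transcripts lack a poly(A) tail, had a median of 0.30, above all 10000 random lists, with 26 of 35 above 0 and 2 (H3c13 and H4c3) at least 2-fold higher. H3c13 was low, at 1.77 FPKM in the knockout library and 0.276 FPKM in the wild-type library. H2bc8 was at 0.90 and H4c11 at 0.76. Ribosomal protein genes had a median of 0.02 (99.9th percentile), with 41 of 77 above 0. Their extremes were Rpl39 at -3.16 and Rps28 at 1.44, with Rps4l at -0.85 and Rpl35a at -0.78, and reads shared with processed copies leave these values uncertain. Random lists were matched on FPKM and not on transcript length, which was not tested for ribosomal protein genes. None of the rows used matched the names of the mitochondrially encoded genes.

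**Figure D2:**
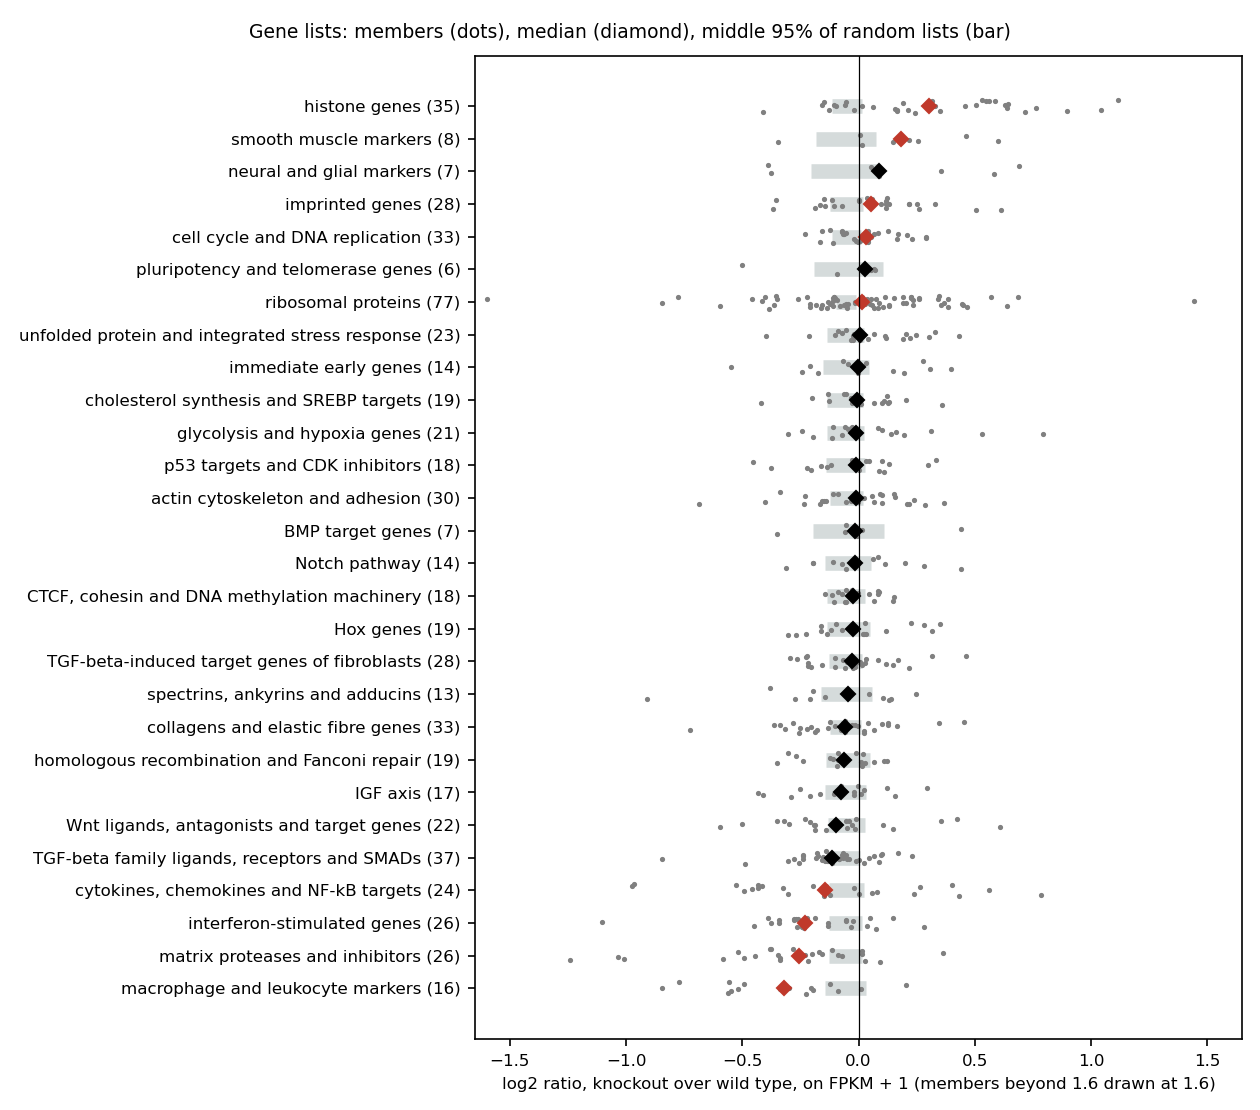
Log2 ratio of knockout over wild-type FPKM + 1 for the 28 gene lists with at least 5 measured members (number in parentheses), with members as dots, medians as diamonds (red where the list stood apart) and bars for the central 95% of 10000 random lists of matched expression. Macrophage markers, matrix proteases, interferon-stimulated genes and cytokine genes have medians below their bars, from -0.32 to -0.14, signs that turn positive on a common FPKM sum, and histone genes have the highest median, 0.30.

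The other lists with a percentile lay inside the central 95%. For signalling, the Notch pathway had a median of -0.02 (72.1st percentile; Heyl at -0.31 and Hey1 at 0.44), and Wnt genes one of -0.10 (11.9th percentile), with Sfrp2 at 0.61, Lgr5 at -0.60 and Myc at -0.50. Immediate early genes were at 0.00 (84.8th percentile), with Maff at -0.55 and Ier3 at 0.40. The pluripotency and telomerase list, with 6 measured members, was at 0.03 (86.0th percentile), and the telomerase gene Tert was listed at 1.47 FPKM in the knockout library and 1.35 FPKM in the wild-type library (0.07). For repair and arrest, homologous recombination and Fanconi genes were at -0.06 (33.3rd percentile), with Xrcc3 at -0.35, Exo1 at -0.30 and Palb2 at -0.27, and p53 targets and CDK inhibitors at -0.01 (86.3rd percentile), with Aen at -0.45 and Gadd45a at 0.33.

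For structure and metabolism, collagen and elastic fibre genes were at -0.06 (42.3rd percentile), with the elastin gene Eln at 13.4 FPKM in the knockout library and 22.8 FPKM in the wild-type library (-0.73) and Efemp1 at 0.45. Actin cytoskeleton and adhesion genes were at -0.01 (87.5th percentile), with the integrin gene Itga2 at -0.68 and the actin gene Actg1 at 0.37. Cholesterol synthesis genes were at 0.00 (91.2nd percentile), with Stard4 at -0.42 and Fdps at 0.36. Glycolysis and hypoxia genes were at -0.01 (87.2nd percentile), with the stress-induced mTORC1 inhibitor gene Ddit4 at 20.6 against 11.5 FPKM (0.80) and Pgam1 at -0.30. Unfolded protein and stress response genes were at 0.00 (93.2nd percentile), with Trib3 at 0.43 and Slc7a3 at -0.40. Hox genes were at -0.03 (67.1st percentile), with Hoxc9 at 0.35 and the joined entry Hoxa5,Hoxa6 at -0.30.

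Markers of further cell types were few among measured genes. Neural and glial markers had 7 measured members and a median of 0.09 (97.2nd percentile), with Fabp7 (27.2 against 16.5 FPKM, 0.69) and Gfap (0.58) on one side and Sox10 (-0.38) on the other. The remaining lists had too few measured members for a percentile. All 4 measured adipocyte markers were below 0, with Fabp4 at -0.53 and Cd36 at -0.43. Of 4 cartilage and bone markers, Col2a1, the main cartilage collagen gene, was at least 2-fold higher at 2.76 against 0.265 FPKM (1.57), and Spp1 at least 2-fold lower. The skeletal muscle list had 1 measured marker (Tnnt2, 0.32), as did the endothelial (Flt1, -0.14), epithelial (Krt18, 0.01) and erythroid (Alas2, 0.27) lists. The Y-linked genes Ddx3y (-0.15), Uty (-0.12), Eif2s3y (-0.07) and Kdm5d (0.03) were measured in both libraries, and Xist, a member of the same list below the measured limit that was chosen after its values were seen, was listed at 0.0410 FPKM in the knockout library and 0.488 FPKM in the wild-type library.

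The authors' deposited table gave a p-value below 0.05 to 1015 rows, of which 371 were higher and 643 lower in the knockout library by FPKM. With 1 library per genotype these p-values hold no spread between cultures. The next counts take genes of the authors' deposited table above 0 in both libraries with a mean of 1 FPKM or more, 1 row per name. Of these genes, 619 had a p-value below 0.05 in the authors' deposited table, and 221 of the 619 differed by less than 0.3 on the log2 scale of the FPKM. For example, Col1a1 (like Actb chosen after its values were seen) was listed at 939 FPKM in the knockout library and 957 FPKM in the wild-type library with a p-value of 0.025612 in the authors' deposited table. Actb, at 1016 against 912 FPKM, had a p-value of 0.59239 in the authors' deposited table. In the authors' deposited table the p-value and fold of 233 genes implied a standard error under 0.5 times that of genes at the same level, 224 of them with a p-value below 0.05. Of the 11033 genes compared, 94.3% lay within 0.5 to 2 times that level. Others lay above 2 times it, among them Spp1 at 4.25 times. In the authors' deposited table the p-values of the 6 genes chosen for the question were 0.0054086 for H19, 0.010322 for Smad3, 0.025832 for Tert, 0.52545 for Cdkn1c, 0.57592 for Igf2 and 0.87918 for Ctcf, with Smad3 and Tert among the 233. Without those 233, the authors' deposited table gave 395 genes a p-value below 0.05, 133 higher and 262 lower in the knockout library.

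**Figure D3:**
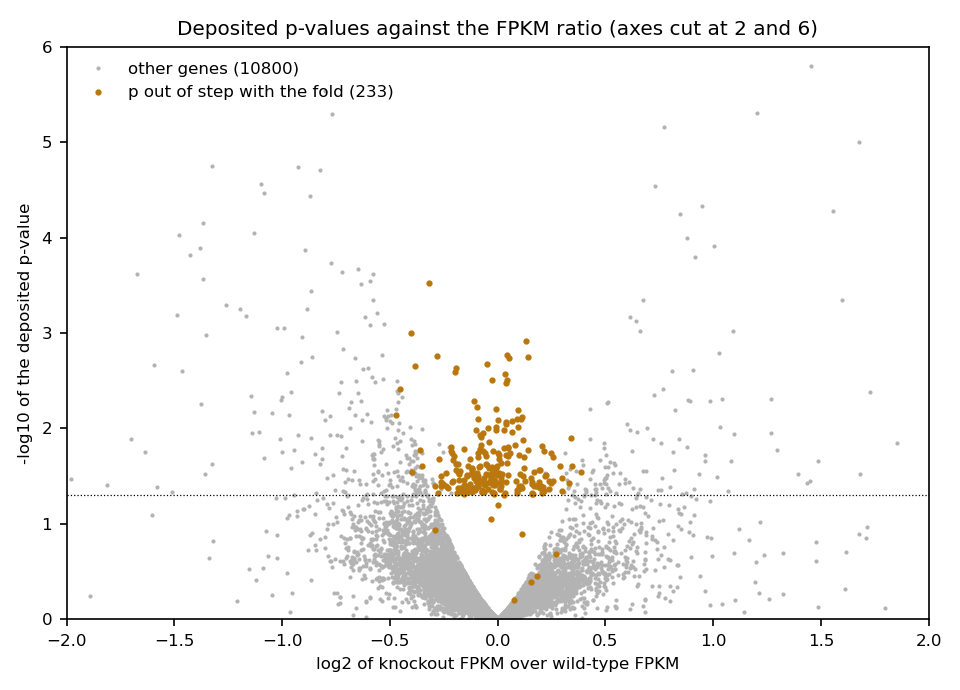
Deposited p-value, as -log10, against the log2 ratio of knockout over wild-type FPKM for measured genes, with the p-value of 0.05 as a dotted line and 233 genes whose implied standard error was under 0.5 times that of genes at the same level in orange. The other genes follow a V shape, and most of the 233 form a separate group near a ratio of 0 just above the dotted line.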

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

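The common FPKM sum without small RNAs and 3 outlying rows was the only setting chosen after the data were seen. Sptbn1 stayed below 0 under every scaling and pseudocount, from -0.93 to -0.45. On a common FPKM sum, genes at least 2-fold higher numbered 104 and lower 26, against 40 and 42, and all 20 negative list medians changed sign, among the lists that stood apart to 0.168 for cytokines, chemokines and NF-κB targets, 0.199 for interferon-stimulated genes, 0.106 for macrophage and leukocyte markers and 0.170 for matrix proteases, since that scaling raises the FPKM ratio of every gene by 0.47 before the pseudocount, which damps it for low genes. It also changed the sign of 33 of 145 named genes. Centring on the median, the upper quartile and the added sum moved FPKM ratios by 0.05 to 0.06 before the pseudocount, changed the sign of 2 named genes each and of 10 to 12 list medians near 0, and gave 41 higher and 38 lower genes each. A mean of 5 FPKM left 25 higher and a 4-fold limit left 10 higher and 19 lower, by fewer genes passing. A pseudocount of 0.1 FPKM gave 72 lower, since it lets low genes move further. The 9 lists kept their side under the pseudocount, no filter, summed rows and 3 of 4 scalings, and 8 of 9 did on a common FPKM sum (cell cycle lost) and at 5 FPKM (cytokines lost; cause not tested). Neural and glial markers joined under all 4 scalings, stress response genes on a common FPKM sum and at 5 FPKM, and immediate early genes at 5 FPKM. Leaving out small RNA genes gave 30 higher and 29 lower. No paired analysis was possible because each genotype has 1 library, nor could a library be left out. Depth is unknown and the knockout library was the shallower, so low and short genes are the least certain.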

Other observations

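Except for the length match of histone genes, all tests here were chosen after the results they measure were seen, as were the 4 gene groups of the next paragraph and the single genes named here outside the fixed rule.

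CXC chemokine genes had 8 of 9 measured entries below 0 and a median of -0.56 (-0.12 on a common FPKM sum). Of the 9, 5 were already on the fixed lists, Cxcl5 and Cxcl10 among them, so the group is not independent of those. The 4 that were not, Cxcl9, Cxcl11, Cxcl14 and Cxcl16, were all below 0, from -0.81 to -0.36. Cxcl11 was at 3.48 FPKM in the knockout library and 6.84 FPKM in the wild-type library and Cxcl14 at 6.21 against 10.0 FPKM, while Cxcl12, a fixed list member, was at 15.7 against 12.9 FPKM. Fc gamma receptors and myeloid C-type lectins, none of them on a fixed list, had 8 of 9 below 0 and a median of -0.37, below the central 95% of random lists (-0.17 to 0.08), which was 0.03 on a common FPKM sum. The inhibitory Fc receptor gene Fcgr2b was at 2.36 against 6.09 FPKM (-1.08) and Clec4n at 6.65 against 12.1 FPKM. The 11 measured entries with H2 names, mostly MHC genes but taking in H2-KE2 and H2-KE6, which do not encode MHC molecules, had a median of -0.15, at the 4.74th percentile, inside the central 95% (0.23 on a common FPKM sum). Nuclear genes of respiratory chain and ATP synthase subunits were higher in 47 of 72, with a median of 0.08. This lay above all 10000 random lists, whose central 95% was -0.10 to -0.01. Measured from the genes nearest in transcript length instead of from 0, their median was 0.11, which is therefore not an increase over 0.08. Their lowest member, Uqcr11, was at 1.13 against 8.28 FPKM. The growth factor gene Ptn was at 270 against 158 FPKM, and the retinoic acid-binding protein gene Crabp2 was lower at 7.23 against 12.4 FPKM.

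Macrophage markers and matrix proteases were lower together in the knockout library. A smaller share of macrophages in that culture is a candidate explanation for the markers, and it needs them to be lower by like amounts. The SD of the 16 log2 ratios was 0.286, above the 0.204 that is the median of matched random lists, but outlying genes carry the range of those lists up to 3.05, so the SD could hardly have excluded this. For the proteases, Mmp3 at -1.04 and Mmp13 at -1.24 both lay below the lowest of the 16 markers, at -0.85. When Fc gamma receptors and myeloid C-type lectins were added, the lowest was Fcgr2b at -1.08, which lay between Mmp3 and Mmp13. That group was chosen after its values were seen, and the outcome turned on this single low gene. The order also depends on the pseudocount, which shrinks the ratio of Fcgr2b more than those of Mmp3 and Mmp13. On plain FPKM ratios Fcgr2b lay below both Mmp3 (-1.05) and Mmp13 (-1.29). The test therefore could not decide whether fewer macrophages account for the proteases. Cell makeup of the culture and an effect of the genotype cannot be told apart with 1 library each, and the latter was not tested.

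Histone genes and RNA polymerase III transcripts were higher in the knockout library. Genes with the name prefixes of micro, small nucleolar, small Cajal body and small nuclear RNAs went both ways (10 at least 2-fold higher and 13 lower). So did the 712 genes under 1000 nt (22 and 22). Among the 9726 genes of 1000 nt or more, 7 were at least 2-fold higher and 15 lower. Among the 632 with no length, 11 were higher and 5 lower. Median log2 ratios ran from 0.03 for protein-coding genes under 600 nt to -0.06 at 7000 nt or more, a span of 0.09. For histone genes the values argue against length as the whole cause. Histone genes lay 0.30 above the 200 other protein-coding genes nearest in transcript length, where length was allowed to leave at most 0.1. The bootstrap 95% range was 0.16 to 0.52, which takes histone genes as independent and reaches below the stricter bound of 0.2 set beforehand. Only 82 other protein-coding genes were under 600 nt and the histone median length was 536.5 nt, so the match drew in longer genes. All 4 measured RNA polymerase III and ribosomal RNA genes were above 0.3, with a median of 0.94. RNA polymerase III transcripts are part of the pattern, and Rn7sk and Rpph1 were already among the highest named genes. These values therefore could not test more RNA without a poly(A) tail as its cause, and 4 genes were too few to decide. The small RNA genes, 10 at least 2-fold higher and 13 lower, showed no shared rise. Their levels are uncertain and they include micro RNA genes, so they did not decide it either. More RNA without a poly(A) tail and an effect of the genotype cannot be told apart with these libraries, and length was not tested for the RNA polymerase III transcripts.

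Of the 14 measured genes among the 10 protein-coding genes on each side of Sptbn1 on chromosome 11, 12 lay within 1.5-fold. Among all measured genes 97.7% did. The median of the 14 was -0.01. The other 2 went opposite ways, Acyp2 at -0.90 (3.03 FPKM in the knockout library and 6.53 FPKM in the wild-type library) and Bod1 at 1.09. Acyp2, 2 places from Sptbn1, was the nearest measured gene on that side, and its ratio was close to the -0.91 of Sptbn1. The next gene, Psme4, was at -0.10, and Bod1 lay 9 places away on the same side. A cause was not tested.

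In the authors' deposited table, 16 log2 values other than 0 differed from the FPKM ratio of their row by 0.496 to 1.96. All 16 had a p-value below 0.05 in the authors' deposited table, 15 were more negative than the FPKM ratio, and all 16 were written with more than 6 significant digits, as was 1 other cell, that of Spp1. For Hprt, at 23.4 FPKM in the knockout library and 31.3 FPKM in the wild-type library, the log2 ratio is -0.42 and the authors' deposited table gives -2.12. For Abcg1, at 1.24 against 1.72 FPKM, these are -0.47 and -2.43 in the authors' deposited table. A further 13 rows of the authors' deposited table gave 0 with a p-value of 1 for unequal FPKM. Genes whose p-value implied a standard error under 0.5 times that of their neighbours in level made up 1.61% of genes in no list and 10.5% of genes in the fixed lists together. They were spread over many lists, with 25.0% of cytokine, 23.3% of actin and adhesion, 23.1% of matrix protease, 21.4% of immediate early and 21.1% of recombination repair genes. They were 14 of 28 TGF-β targets, 12 of 37 TGF-β family genes and 11 of 13 aldehyde dehydrogenase genes (a group chosen after its values were seen), and 0 among interferon-stimulated, macrophage, ribosomal protein and histone genes. The origin of these cells was not tested.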
